A study of Oryza sativa with 52 samples.

How the data were processed

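Total RNA of 52 rice leaf samples was measured on Agilent 2-colour arrays. Per the labels, RNA was reverse transcribed, labelled with Cy3 or Cy5 by a low-input amplification kit and hybridised with 2 different samples on each array, so every sample is 1 channel and no reference RNA was used. No treatment was applied, per the labels. The labels place the field at Fukuoka, while the series' design text names Fukuyama and speaks of 2 developmental stages. Samples were grouped by sampling month and days past transplanting, as the labels give them, into 4 series of 13. Within a series the dye alternated from one time to the next, and the 2 series of a day had opposite dyes at each time.

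Per the file headers, the 26 scanner files hold linear intensity values from Agilent Feature Extraction 10.5.1.1 for each spot: mean and median-background brightness, a processed signal that the software had background-subtracted, detrended and dye-normalized within the array, and flags. The series' value table, as deposited, holds log2 values for 125722 probes. Set against the scanner files, each of its columns followed the processed signal of that sample's own channel (r from 0.9959 to 0.9999 over probes) more closely than that of the other channel of the array (0.9748 to 0.9923). Its column medians lie between 6.36 and 6.37, and it is not centred per probe. How the authors brought the columns to one scale is not given in the sources used here, and 1 sample's processing notes also name affy.

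Mean intensities were background-corrected with normexp (offset 50), normalized within arrays by loess with weight 0 for control spots, and between arrays by the Aquantile method, and each channel was then taken as a log2 value. Control spots and 939 probes with an outlier flag were left out, and probes well above background in at least 13 of the 52 samples in their own channel were kept. The percentage of probes well above background ran from 54.9% to 65.4% per sample, and 1 saturated reading was found. Arrays give no read depth, and precision is limited by their number.

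Models were fitted to all 52 samples in limma 3.58.1 (R 4.3.3, statmod 1.5.0, data.table version 1.17.8) with series means, dye, and cosine and sine terms of period 24 h and 12 h, either shared by the series or separate for each. The array was a random block, with a consensus correlation of 0.441 for the shared curve and 0.328 for separate curves, estimated on 3000 seeded probes. Residual degrees of freedom were 43 and 31. Rhythms and their differences were tested by moderated F-tests of the 4 daily terms, and levels by limma's moderated test of the difference of series means. Calls required a Benjamini-Hochberg adjusted p under 0.05, and "2-fold" also a difference of at least 1 (log2). Peaks were read from the fitted curve on a grid of 0.1 h. Named differences are fitted values with their SE, and levels are means ± SD of the 13 samples of a series, which include the daily change. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

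Probes stand in for genes, because the files used here give no gene names and the gene table at hand holds no sequences to match probes to. The design fixed before the data were examined had a rule for named genes: among called genes with a name, those with the largest rises and falls that moved the same way at 11 or more of 13 matched times, those with the largest rhythms and those with the smallest p for each rhythm difference. After the data were examined, the condition of a name was dropped, overlapping probes were represented by the brightest one, and at most 2 probes per direction were kept. The gene lists and their set test, and the mean over the probes of a gene, could not be run without gene names. Probes with at least 30 bases in common on one strand were joined into sets, 106463 on the array and 65494 among kept probes. A test of whether the rhythm difference between transplantings changes between the days was also added.

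The numbers that the labels imply pair samples of one day and clock time across the 2 transplantings. After subtracting series means, samples of the same time correlated from 0.752 to 0.889 over probes in July and from 0.808 to 0.931 in August, over 13 pairs each, against medians of -0.112 and -0.120 for other times. The shared daily curve alone gives such values. After each series' own curve was removed, samples of the same time still correlated, from 0.10 to 0.615 in July (median 0.293) and from 0.022 to 0.653 in August (0.431), against medians of -0.025 and -0.042 for other times. The pairing comes from the labels, and a fit with each sampling time as a replicate block was run beside the main design, which has no such block.

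The fits were tested on simulated data for 20000 probes. The simulated scatter had a part shared within an array, but no slide effect and nothing shared by samples of the same time. Recovery and false calls below hold for such scatter only, and the real samples of the same time were related. A level difference of 1 (log2) was recovered for 97.0% of changed probes and one of 0.5 for 85.0%, with 7 false calls among 19400 unchanged probes. A shared rhythm of peak-to-trough 1 was recovered for 95.0%, and a rhythm difference between the July series for 49.0% at a size of 1 and 89.0% at a size of 2. With the slide as a fixed block these became 38.0% for a level difference of 1 and 2.0% for one of 0.5, and 10.0% and 60.0% for the rhythm differences of 1 and 2. Alternatives covered the processed signals (minus the 75th percentile), the deposited table, quantile normalization, the filter on dim probes, the array and slide blocks, the 24 h terms alone, single dyes, the second 10:00 sample and a stricter threshold. Slides and the scanning day were read from the file headers. Of these 7 slides, 3 held samples of more than 1 series. For the 2 contrasts with a shared slide, probes were also chosen without that slide's samples, from a fit with the shared curve, and then compared within it. Shared daily curves and their difference between months were also fitted to the mean of the 2 series at each sampling time, without an array block (20 and 16 residual degrees of freedom), since same-time samples are not independent. These checks and the correlations after removal of each series' curve were chosen after the data were seen.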

Results

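Leaves of rice (Oryza sativa, variety Koshihikari) from a paddy field were profiled over 4 daily time courses, to follow how transcript levels change through the day in the field. Each time course, called a series here, held 13 samples taken each 2 h from 10:00 to 10:00 on the next day. On 18 and 19 July 2013 and again on 22 and 23 August 2013, plants of 2 transplantings were sampled at the same times. Seedlings set out on 5 June were 43 days past transplanting in July and 78 days in August, and seedlings set out on 27 June were 21 and 56 days past it. The 52 samples were hybridised as 26 pairs of samples on 2-colour arrays of 60-base probes, spread over 7 slides. No time point of a series had a replicate, and the labels do not say how many plants made up a sample. The p-values below therefore measure the scatter of single samples around smooth daily curves, and a difference between 2 series includes any difference between the plots they came from.

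Between 54.9% and 65.4% of probes were well above background in a sample. The 98576 probes that were so in at least 13 samples, 64.9% of the 151878 on the array, were tested, and they form 65494 sets of probes that share at least 30 bases. The files used here give no gene names for these probes, so each result is given per probe, with the ID and the sequence of a few examples. Over the tested probes, the 1st principal component held 35.3% of the variance and the 2nd held 21.8%, and the clock time explained 81.2% and 90.4% of them. The 3rd held 18.6%, of which the sampling month explained 64.4% and the slide 75.3%. The number of arrays limits the precision of every value.

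Transcript levels of most probes followed the time of day. A daily curve shared by the 4 series was called for 88319 probes (89.6% of those tested), and for 40261 of them (40.8% of those tested) the fitted peak lay at least 2-fold above the trough. The median peak-to-trough difference over all tested probes was 0.83 on the log2 scale, a 1.78-fold change within a day. The largest reached 11.75 (log2), for probe 44kb3_38952 (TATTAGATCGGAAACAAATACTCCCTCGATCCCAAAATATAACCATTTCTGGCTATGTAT), which peaked at 12.1 h clock time with an adjusted p of 3.8e-23. Probe eAry2_46213 (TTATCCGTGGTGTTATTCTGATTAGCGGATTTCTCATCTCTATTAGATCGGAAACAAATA) had a difference of 11.66 and peaked at 11.8 h. Its last bases are the first ones of 44kb3_38952, so both can belong to the same transcript. Later in the day came eAry2_48790 (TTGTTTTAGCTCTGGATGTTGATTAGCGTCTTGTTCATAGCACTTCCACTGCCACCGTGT), with 11.71 and a peak at 16.4 h, and 44kb3_18039 (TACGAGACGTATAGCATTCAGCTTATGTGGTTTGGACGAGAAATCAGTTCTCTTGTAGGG), with 11.14 and a peak at 18.3 h. In each of the 4 series taken alone these 4 probes kept a difference of at least 10.77. Probe 44kb3_18039 was well above background in only 9 of 13 samples at 21 days in July, and the others also fell to low signals at their troughs. The size of these changes may therefore depend on how low signals are treated. The test was limma's moderated F-test of the daily terms, with Benjamini-Hochberg adjustment. Samples taken at the same time in a month are not independent, which makes its p-values too small. The curves also rest on a single day pair in each month.

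**Figure D1:**
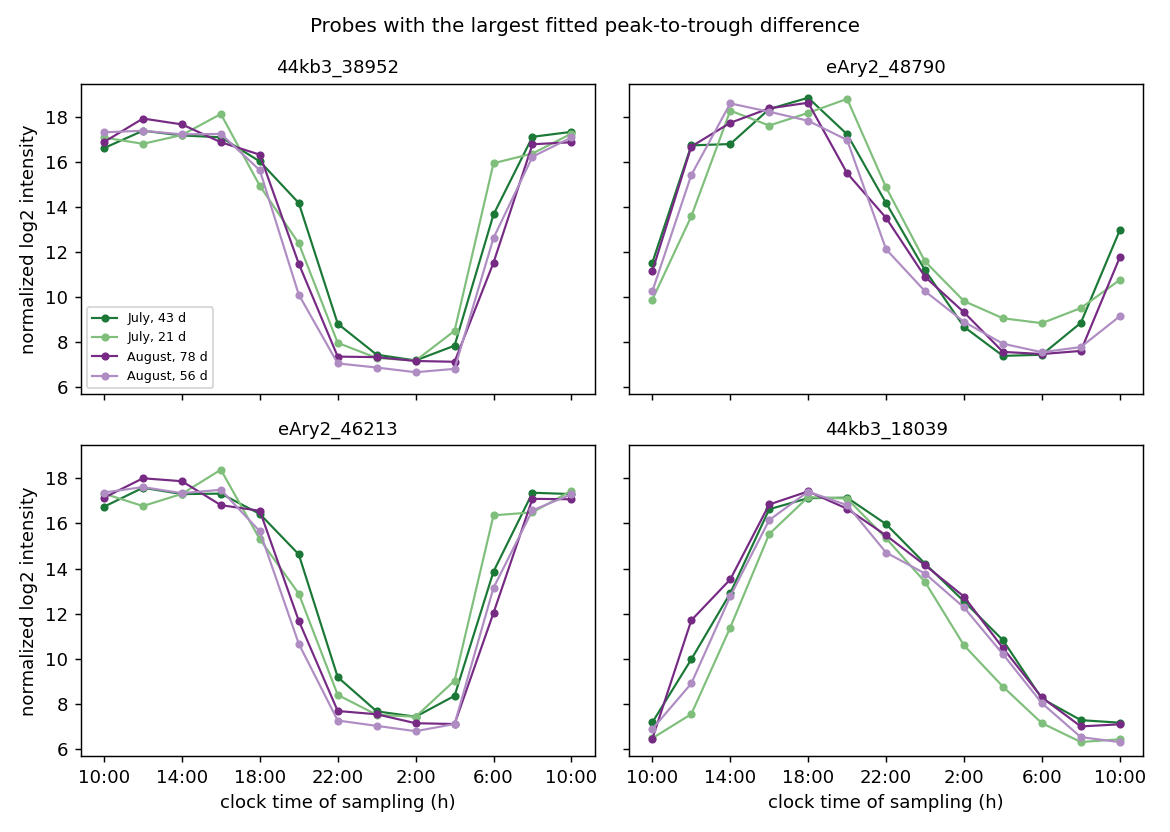
Normalized log2 intensity (vertical axis) against clock time of sampling in h (horizontal axis) for the 4 probes with the largest fitted peak-to-trough difference, with 1 line per series and 1 point per sample. All 4 series follow nearly the same course, with fitted differences between 11.14 and 11.75 (log2).

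Peaks of the 40261 strongly rhythmic probes gathered at 2 times of day. The interval from 14 to 16 h held 15.7% of them and the interval from 6 to 8 h held 13.2%. The fewest peaked from 2 to 4 h (4.5%) and from 20 to 22 h (4.6%). Probes with peaks between 10 and 12 h had the largest median peak-to-trough difference (1.77, log2), and those with peaks from 0 to 4 h the smallest (1.43). Neighbouring probes on one transcript can repeat one another, and 25628 strongly rhythmic probes were counted when each overlapping set had 1 probe.

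**Figure D2:**
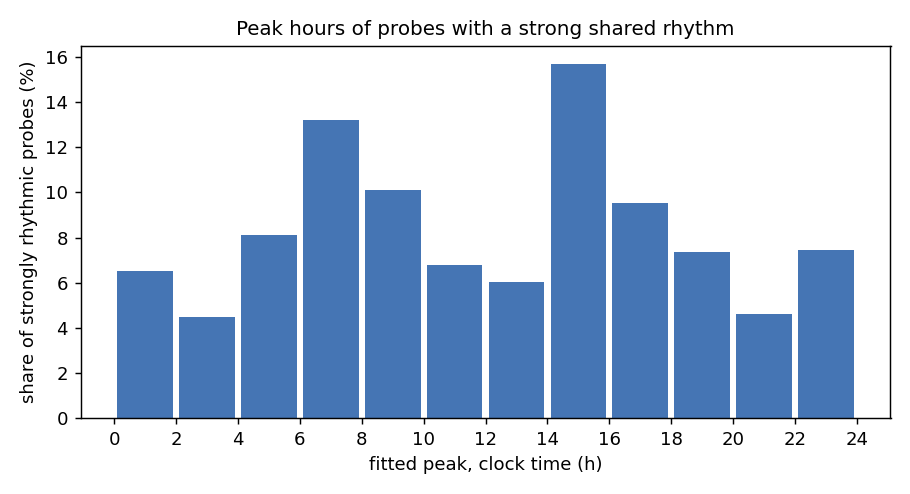
Share of the strongly rhythmic probes in percent (vertical axis) by the clock time of the fitted peak in 2-h intervals (horizontal axis). The tallest bars are those from 14 to 16 h (15.7%) and from 6 to 8 h (13.2%).

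Fitted separately, the 4 series gave 68174 rhythmic probes at 43 days in July, 78448 at 21 days in July, 70348 at 78 days in August and 73647 at 56 days in August. The same call was made in all 4 series for 51188 probes (51.9%). Over the strongly rhythmic probes, the median peak-to-trough difference was smallest in the July series at 43 days (1.62, log2) and largest in the July series at 21 days (1.90). The August series lay between them, with 1.73 at 78 days and 1.78 at 56 days. Between the 2 July series, 29.8% of these probes had the larger difference at 43 days. With the slide as a fixed block the July medians were 1.68 at 43 days and 1.96 at 21 days. Samples of a single dye gave 26886 to 50775 rhythmic probes per series.

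In July, leaves of the earlier transplanting differed from those of the later one in the daily mean level of 56176 probes, 30872 higher and 25304 lower at 43 days. A difference of at least 2-fold was found for 4407 probes, of which 1710 were higher and 2697 lower at 43 days. The largest excess at 43 days in the main fit was that of probe PPNTpc_00175 (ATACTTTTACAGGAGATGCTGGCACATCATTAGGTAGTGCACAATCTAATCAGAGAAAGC). Its log2 level was 12.14 ± 0.83 (SD, n = 13) at 43 days and 7.01 ± 0.76 at 21 days, where it was well above background in 8 of 13 samples. The fitted difference was 5.20 ± 0.25 (SE, log2), with a limma adjusted p of 1.2e-17, and 6.55 with the processed signals, so its size depends on how the dim signals at 21 days are treated. Probe PPNTnpc_01705 (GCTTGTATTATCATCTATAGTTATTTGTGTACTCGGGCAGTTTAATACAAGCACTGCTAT) was 29.7-fold higher, by 4.89 ± 0.21 (log2). With the slide as a fixed block its difference, 4.24, was slightly above the 4.20 of PPNTpc_00175. In the other direction, eAry2_25535 (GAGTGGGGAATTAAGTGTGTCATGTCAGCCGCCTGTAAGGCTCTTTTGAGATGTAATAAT) was 65.3-fold lower at 43 days (-6.03 ± 0.23, log2), and eAry2_07291 (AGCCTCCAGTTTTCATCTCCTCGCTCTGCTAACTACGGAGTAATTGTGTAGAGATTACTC) was 19.2-fold lower (-4.26 ± 0.40). These 4 probes differed the same way at all 13 matched times.

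Over intervals of peak time, the median July difference of strongly rhythmic probes ran from -0.20 (log2, 43 days minus 21 days) for peaks from 8 to 10 h to 0.33 for peaks from 14 to 16 h. These intervals were not tested against one another. Most samples of a series shared slides with no sample of the other, so slide and series overlap. A fixed block for the slide called 2365 probes, 2164 of them among the 56176, and 1614 at 2-fold, 899 of them among the 4407. The share of calls higher at 43 days moved from 55.0% to 39.3%, and the median SE rose from 0.08 to 0.26 (log2). The folds changed less than the counts: over the 4407 probes the median difference went from 1.26 to 1.13 (log2) for higher and from -1.32 to -1.27 for lower ones. Of the 4407 probes, 94.6% had the same sign under the block, 99.0% within slide 2, which held 5 samples of the older plants and 3 of the younger, and 94.4% on the 1 array that paired the 2 series. Sign agreement is partly built in there, as the probes were chosen on these samples too. Chosen without the samples of slide 2, 4406 probes differed by at least 2-fold, and 89.3% of them had the same sign within slide 2, with medians of 1.13 and -1.01 (1.25 and -1.33 outside it), and 90.6% on that array. Slide 2 held the last samples of the older plants and the first of the younger, so its values rest on removal of the shared daily curve. That array paired the second 10:00 of the older plants with the first 10:00 of the younger. The 4 named probes kept adjusted p-values of 0.0207 or lower with the slide block, and the median became -0.11 for peaks from 8 to 10 h and 0.25 for peaks from 14 to 16 h.

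In August the 2 transplantings differed less. The daily mean level differed for 22729 probes, 11896 higher and 10833 lower at 78 days, and by at least 2-fold for 1631 probes, 377 higher and 1254 lower. Probe eAry1_26111 (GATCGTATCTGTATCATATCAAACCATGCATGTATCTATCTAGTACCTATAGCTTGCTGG) had a log2 level of 11.27 ± 0.76 (SD, n = 13) at 78 days and 7.79 ± 0.52 at 56 days. The fitted difference was 3.46 ± 0.17 (SE, log2), with a limma adjusted p of 3.3e-16. Probe eAry2_43983 (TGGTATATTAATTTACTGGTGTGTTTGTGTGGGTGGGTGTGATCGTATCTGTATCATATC), which shares fewer than 30 bases with it but can belong to the same transcript, was higher by 3.39 ± 0.19 (log2). Lower at 78 days were 44kb3_19244 (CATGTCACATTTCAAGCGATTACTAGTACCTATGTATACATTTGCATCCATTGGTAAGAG), by 15.9-fold (-3.99 ± 0.17), and eAry2_20235 (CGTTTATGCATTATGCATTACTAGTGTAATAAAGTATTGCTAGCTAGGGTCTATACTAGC), by 14.8-fold (-3.89 ± 0.16). All 4 differed the same way at each of the 13 matched times, where again 11 or more was a condition of their choice.

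Under a fixed block for the slide the August count was 380, of which 290 were among the 22729, with 309 at 2-fold, of which 148 were among the 1631. The share of calls higher at 78 days moved from 52.3% to 23.7%. Over the 1631 probes the median difference was 1.28 without and 1.33 with the block for higher ones, and -1.33 and -1.35 for lower ones, while the median SE rose from 0.08 to 0.25. Of the 1631 probes, 96.3% had the same sign under the block, 97.8% within slide 6, which held 7 samples at 78 days and 1 at 56 days, and 94.2% on the 1 array shared by the 2 series, with sign agreement again partly built in. Chosen without the samples of slide 6, 1178 probes differed by at least 2-fold, and 87.4% of them had the same sign within that slide, with medians of 0.56 and -1.01 (1.36 and -1.32 outside it), and 85.9% on that array, both resting on a single sample at 56 days. Without the 4 samples at 56 days whose slide was scanned on another day, 9794 probes were called. Single dyes gave 4691 (Cy3) and 4530 (Cy5).

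The level difference between the series of the 2 transplantings was not the same on the 2 days. The test of the August difference against the July difference called 39239 probes, 19873 with the larger value in August and 19366 with the smaller one. Over all tested probes the 2 differences had a correlation of 0.02, across probes that are not independent of one another. Of the 14686 probes called on both days, 62.2% differed in the same direction. Among the fewer probes with differences of at least 2-fold on both days, the most frequent combination was higher in the older plants in July and lower in the older plants in August. It was seen for 404 probes, where independent lists of these sizes share 21.8. The opposite combination was seen for 57 probes against 10.3. Higher on both days were 56 against 6.54, and lower on both days were 82 against 34.3. Probe 44kb3_19244 was higher in July and lower in August in the older plants, with 13.34 ± 0.78 (SD) at 43 days and 9.61 ± 0.63 at 21 days in July against 10.68 ± 1.17 at 78 days and 14.66 ± 1.04 at 56 days in August. The slide block called 1469 probes for the difference between days, of which 1214 were among the 39239.

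**Figure D3:**
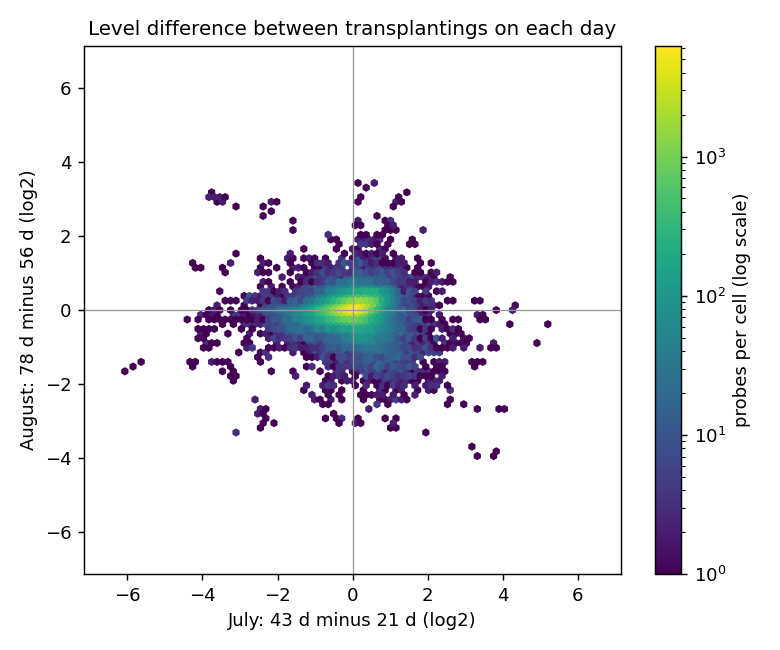
Difference in daily mean level between the 2 transplantings (log2) in August (vertical axis, 78 days minus 56 days) against July (horizontal axis, 43 days minus 21 days) for the 98576 tested probes, with the colour giving the number of probes per cell on a log scale. The cloud has no slope, with a correlation of 0.02 over probes.

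Plants of one transplanting changed between July and August, when age and calendar date moved together. For the earlier transplanting, 45287 probes differed between 43 and 78 days, 24674 higher and 20613 lower in August, and 5465 did so by at least 2-fold (2569 higher, 2896 lower). For the later transplanting, 66176 probes differed between 21 and 56 days, 34532 higher and 31644 lower in August, and 12541 did so by at least 2-fold (6006 higher, 6535 lower). The 2 contrasts have no samples in common, and their effects had a correlation of 0.70 over probes. Both called 1829 probes at least 2-fold higher in August, where independent lists share 157, and 2213 at least 2-fold lower, where they share 192. Opposite directions were seen for 53 and 69 probes, against 170 and 176.

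In the earlier transplanting, 44kb3_38262 (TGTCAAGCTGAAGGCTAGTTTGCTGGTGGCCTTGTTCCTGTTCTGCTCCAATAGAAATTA) rose from July to August by 6.30 ± 0.18 (SE, log2). It was dim in July, well above background in 8 of 13 samples, and the size of the rise depends on how low signals are treated: the rise was 7.97 in the processed signals and 7.98 in the deposited table. Probe 44kb3_24139 (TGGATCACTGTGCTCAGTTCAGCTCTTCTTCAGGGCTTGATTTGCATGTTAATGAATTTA) rose 44.3-fold (5.47 ± 0.45). Probe eAry2_40456 (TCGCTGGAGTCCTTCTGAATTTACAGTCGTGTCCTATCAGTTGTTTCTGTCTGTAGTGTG) changed by -7.75 ± 0.42 (log2) and eAry1_27418 (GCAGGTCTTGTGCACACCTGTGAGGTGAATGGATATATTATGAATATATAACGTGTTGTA) by -7.73 ± 0.36. Both were near background in August, well above it in 1 and 2 of 13 samples, so the size of these falls is set by how low signals are treated, and the processed signals gave -10.91 and -11.14.

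In the later transplanting, PPNTpc_00175, the probe with the largest July excess at 43 days in the main fit, rose by 9.13 ± 0.25 (log2) between 21 and 56 days, to 16.07 ± 0.34 (SD, n = 13). Probe eAry1_14244 (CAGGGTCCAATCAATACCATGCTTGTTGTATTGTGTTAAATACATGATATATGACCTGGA) rose by 7.68 ± 0.22 (SE). Both were dim at 21 days, well above background in 8 and 9 of 13 samples, and the processed signals gave rises of 10.33 and 8.88. Probe 44kb3_20070 (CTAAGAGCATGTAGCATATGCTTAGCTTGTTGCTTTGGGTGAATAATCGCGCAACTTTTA) fell by 7.20 (log2, SE 0.35), and eAry1_27418 again fell by 7.03 (SE 0.36). The largest limma adjusted p among the named probes of both contrasts was 5.4e-12, and all of them moved the same way at all 13 matched times. With the slide as a fixed block, 6803 probes (4542 at 2-fold) were called for the earlier and 7197 (6286) for the later transplanting, of which 5279 (1981) and 6808 (3896) were among the calls above. The named probes kept adjusted p-values of 0.0129 or lower. The share of 2-fold calls that were higher in August moved under the block from 47.0% to 58.0% and from 47.9% to 58.6%. Of the 2-fold probes, which were chosen on these same samples, 91.3% and 94.4% had the same sign. Their median differences went from 1.34 to 1.32 and from -1.37 to -1.19 in the earlier transplanting, and from 1.52 to 1.51 and from -1.45 to -1.27 in the later one. No slide held both series of either contrast, so a value within a slide cannot be given. With the processed signals, 10919, 3575, 11530 and 21651 probes differed by at least 2-fold in the July, the August and these 2 contrasts, and of the calls at any size fewer than 50% were higher in the older plants or in August (48.0%, 48.0%, 46.7% and 43.7%).

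**Figure D4:**
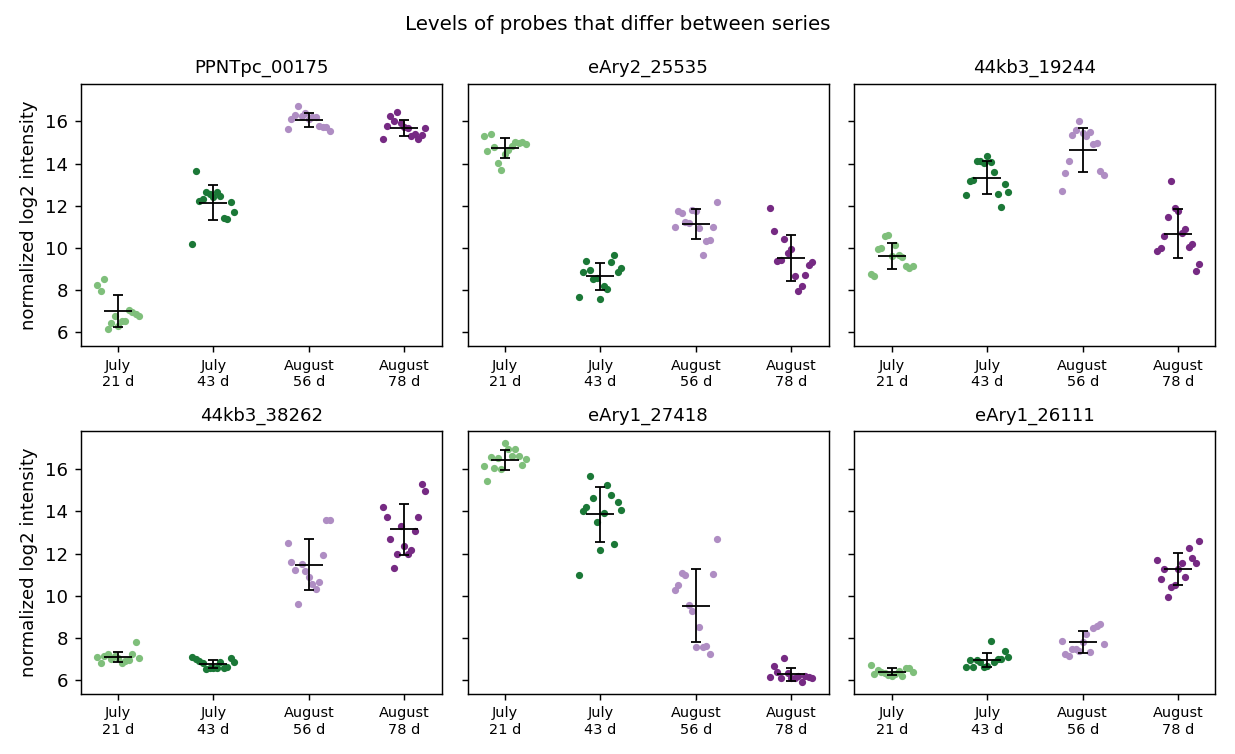
Normalized log2 intensity (vertical axis) of 6 named probes in the 4 series (horizontal axis, month and days past transplanting), with 1 point per sample, set in sampling order, and bars for mean ± SD (n = 13). PPNTpc_00175 goes from 7.01 at 21 days to 16.07 at 56 days, and eAry1_27418 from 16.46 at 21 days to 6.27 at 78 days.

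The daily course of many probes differed between the months. The test of the daily terms, mean of the August series minus mean of the July series, called 41366 probes. The 2 series of a month were sampled at the same times of one day pair and their scatter was related, which makes these p-values too small. With 1 mean of the 2 series per sampling time, 39157 probes were called, of which 36115 were among the 41366, and the count still compares 1 day pair per month. Of the 41366, 49.1% had the larger peak-to-trough difference in August. It was larger by at least 1 (log2) in August for 3366 probes and in July for 3113. Probe 44kb3_3737 (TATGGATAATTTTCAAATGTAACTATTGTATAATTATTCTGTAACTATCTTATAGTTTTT) had a daily change of 4.12 and 5.57 (log2) in the July series at 43 and 21 days, with peaks at 9.5 and 8.9 h, and was not well above background in any sample at 78 days. Its adjusted p was 1.3e-11. Probe eAry2_02430 (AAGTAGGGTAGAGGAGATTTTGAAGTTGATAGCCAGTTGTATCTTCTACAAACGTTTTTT) went from 7.23 and 8.10 in July to 1.33 and 3.26 in August at 78 and 56 days, where it was well above background in only 5 and 6 of 13 samples. The slide as a fixed block gave 16827 calls, of which 15582 were among the 41366, and with Cy3 or Cy5 samples alone, which leave 6 residual degrees of freedom, 524 and 870.

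Between the 2 July series the daily course differed for 4943 probes, and 79.6% of them had the larger peak-to-trough difference at 21 days. It was larger by at least 1 (log2) at 21 days for 1273 probes and at 43 days for 433. An example in the less frequent direction is PPNTnpc_01384 (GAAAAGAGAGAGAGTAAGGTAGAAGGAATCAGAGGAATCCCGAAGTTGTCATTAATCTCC), with 4.03 at 43 days and 0.33 at 21 days (adjusted p 8.4e-08), well above background in 4 of 13 samples at 21 days. Probe eAry2_01807 (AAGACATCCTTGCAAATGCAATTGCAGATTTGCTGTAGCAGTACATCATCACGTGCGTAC) had 4.02 with a peak at 2.4 h at 43 days and 2.34 with a peak at 11.2 h at 21 days. When the slide was a fixed block the July count was 165, of which 147 were among the 4943, and 73.5% of the 4943 still had the larger value at 21 days. With Cy3 samples alone 0 probes were called and with Cy5 samples alone 10, and both named probes lost their call there.

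Between the 2 August series the daily course differed for 6 probes, and the test of whether this difference itself changed between the days called 104. The smallest August p-values were those of PPNTnpc_01951 (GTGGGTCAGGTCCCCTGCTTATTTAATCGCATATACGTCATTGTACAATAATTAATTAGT), at 0.0031, and eAry2_09088 (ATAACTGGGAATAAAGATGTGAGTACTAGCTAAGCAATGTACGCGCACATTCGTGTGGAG), at 0.018, both adjusted. The first had a daily change of 2.80 (log2) at 78 days and 1.09 at 56 days, and the second 1.87 and 4.22. Both calls ended with the slide as a fixed block (adjusted p 0.872 and 0.185), with the processed signals (0.114 and 1), with single dyes, with the 24 h terms alone and without the second 10:00 samples. The deposited table, which holds the second of them, gave 0.946, and the processed signals called 4 probes, of which 1 was among the 6. The slide block gave 0 August calls and 2 calls of the difference between days, and leaving out the slide scanned on another day raised the August count to 141.

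Over the 40261 strongly rhythmic probes, the fitted peak was later in August than in July by a circular median of 0.4 h, and 73.6% of peaks lay within 2 h of each other. Among the 20337 of them whose daily course differed between the months, 4616 peaked over 2 h later and 3086 over 2 h earlier in August. The median shift was 0.1 h between the July series, 0.0 h between the August series, 0.2 h from 43 to 78 days and 0.5 h from 21 to 56 days. Probes with peaks from 20 to 22 h (1.1 h) and from 10 to 12 h (1.0 h) had the largest shifts, and those with peaks from 0 to 2 h moved the other way (-0.5 h). With the slide as a fixed block the median shift from July to August was 0.1 h.

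The time printed on a sample could be read back from its transcripts. For each sample, the hour was predicted from the curves of the other 3 series, over 39627 to 42351 strongly rhythmic probes. The median absolute error was 0.4 h, the largest was 1.0 h, and so all 52 samples fell within 1 h of their labelled time. The mean error was 0.10 ± 0.49 h (SD, n = 13) at 43 days and 0.34 ± 0.31 h at 21 days in July, and -0.31 ± 0.41 h at 78 days and -0.19 ± 0.42 h at 56 days in August.

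**Figure D5:**
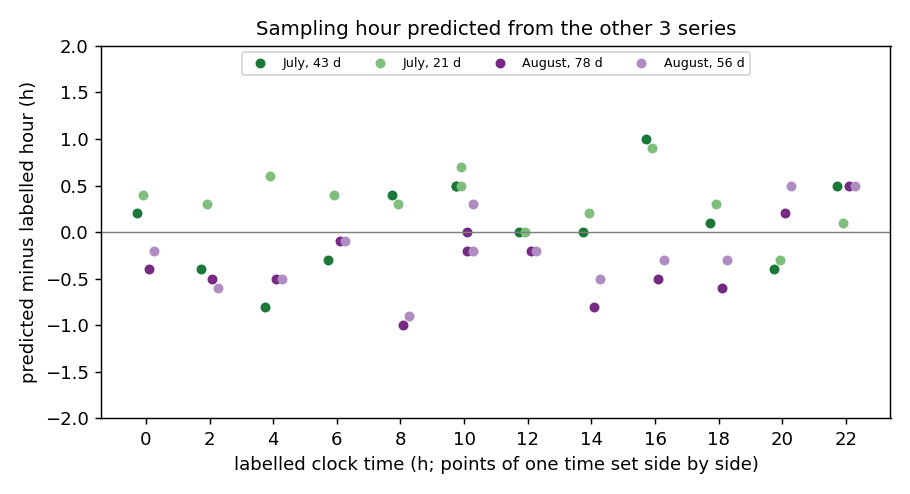
Predicted minus labelled hour in h (vertical axis) against the labelled clock time in h (horizontal axis) for the 52 samples, coloured by series, with the points of one time set side by side. All errors lie between -1.0 and 1.0 h.

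The clock time of 10:00 was sampled on both days of each series. Second minus first, the log2 differences had an SD over probes of 0.49 and 0.45 in the July series at 43 and 21 days, and of 0.37 and 0.54 in the August series at 78 and 56 days. Paired by series (4 pairs), limma called 0 probes after adjustment, with a smallest adjusted p of 0.347, and 11093 had an unadjusted p under 0.05. The change from one day to the next was alike in the 2 series of a day, with correlations over probes of 0.58 in July and 0.61 in August. Between series of different months the correlations lay from -0.08 to 0.05. The test of whether the change differed between August and July called 2555 probes. The 2 series of a month share one pair of mornings and are not independent replicates of it, so the p-values of that test are too small and the count compares these 2 pairs of mornings.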

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

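Chosen only after the results were seen were the test of the rhythm difference between the days, the splits of centred series, the correlation test of slides for the second 10:00, the simulated count under the slide block, the test within slide 2 and the fit to averaged series.

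Differences between groups in the same contrast were called in 6 tests. The level difference between transplantings changed between the days for 39239 probes, and only the labelled split of 100 splits within matched clock times gave as many (1 of 100, highest other 26646). The single level contrasts, again with only the labelled split among 100 reaching the real count, had 56176 probes between transplantings in July (highest other 41926), 22729 in August (11116), 45287 from July to August in the earlier transplanting (11646) and 66176 in the later one (51175). So random assignment of samples at matched times rarely gives such counts, at a share that cannot go below 1 of 100. The samples of a series are not replicates, so any steady offset between series, such as one of plot or slide, would do the same. Slides as the whole cause of the 2-fold July differences are argued against, since 89.3% of 4406 probes chosen without slide 2 had the same sign within it, by medians of 1.13 and -1.01 (log2). That slide holds late samples of one series and early ones of the other, so the comparison relies on removal of the shared daily curve. For the earlier transplanting from July to August, the 5465 2-fold probes kept medians of 1.32 and -1.19 (log2) under the slide block. Chosen on these same samples, 91.3% kept their sign, at a median SE of 0.28, so the agreement is partly built in. No slide held both series, and the block ties them only through 3 samples at 21 days on slide 2 and 2 on slide 5. These values therefore do not decide on slides as the whole cause. Slides stay open for smaller July differences, for the August contrast and for both contrasts from July to August. In the August contrast and in the later transplanting the block ties the August series at 56 days to the others through 1 sample. Plots stay open for all contrasts.

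Daily curves differed between July and August for 41366 probes, and for 39157 with the 2 series of a month averaged at each sampling time. Of 100 splits, 2 gave as many or more (highest other 54047), and after each series was centred on its own mean 1 did (highest other 4695). For the rhythm difference between transplantings, 18 of 100 splits reached the 4943 probes of July (highest other 33157), 23 reached the 6 of August (highest other 1885) and 12 reached the 104 whose difference changed between days (highest other 9844). Chance assignment is not excluded for these 3 by the splits of uncentred values, which cannot decide on it. Splits that call several times the real count point to a structure of the samples: exchanging samples between series with different levels turns a level difference into an apparent daily curve. After centring, 1 of 100 splits reached the July count (highest other 1747), 3 the August count (highest other 8) and 2 the count between days (highest other 202). The labelled split is among these numbers, so random assignment of centred samples rarely gave such counts. Slides and plots stay open.

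The weaker daily change at 43 days in July was weighed against 3 technical explanations. A narrower signal range is argued against, since the log2 range of the spike-in controls was 2.58% smaller at 43 than at 21 days, under the 5% named beforehand. Harvest off the labelled hour is argued against too, as 4577 probes were called with the predicted hours. Slide differences stay open: with the slide as a fixed block the July count fell from 4943 to 165, as predicted for that cause, and data simulated without any slide effect still gave 960 under the block and 4275 without it. The simulation kept the fitted July differences of the 4943 called probes and gave the others none. Differences selected by a test tend to be too large, so 960 may be too high. The block also costs power, since a slide holds runs of neighbouring times of a series, and the median peak-to-trough difference stayed larger at 21 days (1.96 against 1.68, log2). How much of the count slides account for thus cannot be told, and a difference between the plants remains an open and untested alternative.

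The change from the first to the second 10:00 differed between August and July for 2555 probes. These p-values are too small because the 2 series of a month share one pair of mornings. As changed alike in all series, 0 probes were called (11093 at an unadjusted p under 0.05 in limma). On simulated data this test with 4 pairs recovered 65.5% of changes of 1 (log2), so a common change is not excluded. For that count of 0, the 8 sign patterns of the 4 series cannot decide, since every pattern reaches a count of 0 (8 of 8 did, highest other 0). They would also be too few for a share under 0.05. Within a day the 2 series changed alike, and slides are argued against, because the slide that 2 series of a day share holds late samples of one and early samples of the other and would push their changes apart, yet the lower of the 2 correlations was 0.577. Harvest at another point of the morning is argued against as well, since that value was 0.583 after each sample was moved to its predicted hour. Conditions of the mornings that both plantings shared, and a shared handling of same-day RNA, both stay open and untested.

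Outside the measured probes, control spots whose names start with DCP were well above background in 87.2% of readings, and the control spot ETG10_236652 in 35.6%, against 1.33% for the negative control.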

How the results depend on the processing

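Chosen only after the data were seen were the settings with 1 probe per overlapping set or the mean over each set, the one without the slide scanned on another day and the one with the mean of the 2 series at each sampling time, as well as the count of probes whose rhythm difference changed between days; the other settings were fixed before the data were examined.

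Of the values recomputed for counts and summary measures, 242 stayed within 1.5 times the first value or within their spread and 108 moved further. Of 382 values for named probes, 365 kept their call and direction and 17 lost the call, all of them for rhythm differences between transplantings. Quantile normalization over all channels moved 0 of these counts past that limit. Signal over background limits the size of differences for probes near background, such as eAry2_40456 (-7.75 against -10.91 with the processed signals). The cause of the other moves was not tested, except where fewer samples or probes explain them.

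Paired by sampling time (replicate block), 57151 probes differed in level between the July series (4060 at 2-fold) and 25176 between the August series (1707), and the difference between days was called for 40268. It changed the call of none of the 8 named probes it was run on, and moved no count by over 1.5 times.

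Counts of 2-fold level differences are given in the order July transplantings, August transplantings, earlier transplanting from July to August, later transplanting from July to August. They were 10919, 3575, 11530 and 21651 with the processed signals, against 4407, 1631, 5465 and 12541. The deposited table gave 9262, 2949 and 9677 for the first 3, and raised the share of the July calls that were higher at 43 days from 38.8% to 49.3%. Only probes above background in all samples gave 2899, 1004, 3387 and 8343, from 70244 tested probes in place of 98576. The SD of the change at the second 10:00, on average 0.461, became 0.689 with processed signals and 0.682 with the deposited table.

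Which direction held more calls changed with the setting. In the same order, 55.0%, 52.3%, 54.5% and 52.2% of level calls were higher, against 48.0%, 48.0%, 46.7% and 43.7% with the processed signals. The second share was also 48.1% with the 24 h terms alone and 47.5% at an adjusted p under 0.01, and the fourth 49.9% with only probes above background in all samples. At 2-fold, the deposited table moved the fourth from 47.9% to 51.0%. The difference between days, near even at 50.6%, ran from 45.3% to 56.8% over the settings.

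With the slide as a fixed block, level counts were 2365, 380, 6803 and 7197, and 1614, 309, 4542 and 6286 at 2-fold, with 1469 for the difference between days. The block widened the median SE from 0.08 to between 0.25 and 0.38 (log2), which lowers the counts by its construction. The share of higher calls moved from 55.0% to 39.3%, from 52.3% to 23.7%, and at 2-fold from 47.0% to 58.0% and from 47.9% to 58.6%. Rhythm differences were 165 in July, 0 in August, 16827 between months and 2 for their change between days, and the peak shift fell from 0.4 h to 0.1 h.

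Counts of rhythm differences between transplantings in July, in August and of their change between days (4943, 6 and 104) moved under most settings. They were 14775, 184 and 1399 without the array block, 8702, 66 and 445 with the slide as a random block, 2786, 0 and 43 with the 24 h terms alone, and 1655, 1 and 12 at an adjusted p under 0.01. The deposited table gave 3104, 0 and 44. The last 2 were 0 and 46 without the second 10:00 samples, 0 and 22 with only probes above background in all samples, and 141 and 160 without the slide scanned on another day. Processed signals gave 20 for the change between days, and no filter on dim probes 18 for August. Between months, the 24 h terms alone gave 26734 and the stricter threshold 24429 in place of 41366. That threshold gave 13871 level differences between the August series, and leaving out the slide scanned on another day 9794, with the share higher at 78 days falling from 52.3% to 42.0%.

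Single dyes leave fewer samples and 6 residual degrees of freedom. Rhythmic probes at 43, 21, 78 and 56 days were then 34445, 39528, 33129 and 38216 (Cy3), and 26886, 50775, 34440 and 36838 (Cy5). Level counts were 34917 and 31242 in July, 4691 and 4530 in August, 25190 and 21281 from July to August in the earlier transplanting, and 15367 and 15707 for the difference between days. The August share higher at 78 days was 34.7% and 32.7%. Rhythm differences were 0 and 10 in July, 0 and 0 in August, 524 and 870 between months, and 0 and 0 for their change between days.

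Using 1 probe per overlapping set, or the mean over each set, leaves 65494 tests and lowers counts by that construction. Shared rhythms were 58073 and 58266, strong ones 25628 and 25327, and rhythmic probes at 43, 21, 78 and 56 days 44557 and 45011, 51418 and 51720, 45809 and 46269, and 48081 and 48533. Level counts were 14741 and 15037 in August, 29972 and 30152 from July to August in the earlier transplanting and 43644 and 43948 in the later one. At 2-fold they were 2871 and 2803 in July, 1077 and 1051 in August, and 3464 and 3369, and 8028 and 7900, from July to August. Rhythm differences were 3016 and 3101 in July and 26572 and 27368 between months, and 66 with 1 probe per set for their change between days.

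Not run for want of gene names were the mean over the probes of a gene and both forms of the set test on gene lists.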

Other observations

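Chosen only after the result was seen were the tests on opposite strands, while the test of plant age was fixed beforehand and its reading was changed afterwards.

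The difference in peak-to-trough between the July series varied with the interval of peak time. Probes with peaks from 14 to 16 h had a median peak-to-trough difference of 1.35 (log2) at 43 days and 1.98 at 21 days, and with the slide as a fixed block 1.46 and 1.95. Those with peaks from 6 to 8 h had 1.69 and 2.06, and 1.71 and 2.17 with the block, and those with peaks from 16 to 18 h 1.68 and 1.87. Probes with peaks from 10 to 12 h had 2.01 and 2.07, and 2.13 and 2.26 with the block. At the second 10:00 of the August series, probes that peak from 10 to 12 h were lower than at the first, by medians of -0.30 (log2) at 78 days and -0.60 at 56 days. Those that peak from 20 to 22 h were higher, by 0.30 and 0.47. In July the same groups had medians between -0.14 and 0.03. These groups were not tested against one another.

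Kept and rhythmic shares differed with the prefix of the probe name, whose meaning is not given in the sources used here. Of probes starting with 44kb3, 80.7% were kept and 43.8% of the kept ones were strongly rhythmic. Of those starting with Cuffnpc, 26.1% were kept and 23.6% of these were strongly rhythmic, at a median log2 intensity of 7.07 against 10.0.

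Probes for opposite strands of one sequence often both gave signal. Of 1841 such pairs on the array 1033 had both probes kept, and their median correlation over the 52 samples was 0.16, against 0.97 for overlapping probes of one strand and 0.00 for random pairs. Labelling of both strands is argued against as the whole cause: it would make the dimmer probe follow the brighter, but in 377 pairs at least 8-fold apart the median correlation was 0.113, and -0.218 in the 154 of them with both probes well above background in all samples. A general excess of opposite daily timing is argued against too, because among 110 pairs with strong rhythms on both strands 26.4% had peaks at least 8 h apart, against 33.6% of random strong pairs. With both probes well above background in all samples it was 34.4% of 64 pairs, against 34.2% of random ones, too few pairs to exclude a small excess. More of these pairs than of random ones peaked within 2 h of each other (36.4% against 18.7%, and 28.1% against 18.7% with both probes well above background in all samples, not tested), so labelling of both strands stays open for a part of the pairs. Separate transcripts from both strands and probes that bind other transcripts remain untested alternatives.

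Whether levels are set by days past transplanting cannot be decided from these series. Were change even with age, the 2 series closest in age, 56 days in August and 43 days in July, would differ least, although they differ in month and transplanting. The SD over probes of their difference was 0.539 (log2), above the 0.484 between 43 and 21 days in July and the 0.308 between 78 and 56 days in August. The pair differed by at least 2-fold for 6192 probes, against 4407 and 1631. An SD at or above that 0.484 had been named beforehand as going against levels set by age, and the value met this. That reading was dropped afterwards because each series has its own age. A step between 43 and 56 days could give such values, as could a difference of month or slide.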
